A study of Homo sapiens with 6 samples.

How the data were processed

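RNA from RKO cells, an established human line from a poorly differentiated colon carcinoma, was profiled by total RNA sequencing in 6 libraries: 3 carrying a short hairpin RNA against TRIM21 (shTRIM21) and 3 carrying a scrambled hairpin (shControl). Per the labels' protocols, hairpins were delivered by lentivirus, puromycin at 5 µg/ml was added 36 h after infection and kept for weeks, and libraries were made from total RNA after ribosomal RNA depletion with GenSeq kits. One label field calls the source mouse tissue, while the organism, the cell line and the gene symbols are human, so the samples were treated as human cells. Groups and replicate numbers came from the sample titles. The labels call the samples biological replicates but give no separate infections, so p-values of single genes measure the spread between these libraries. Each arm holds 1 hairpin or pool as far as the labels say, and the hairpin sequences are not given in the sources used here.

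The authors deposited raw read counts per gene symbol, 1 table of 28278 rows per library, with no normalization. TopHat2, edgeR 3.38.1, limma 3.52.2 and the build hg38 are named in the submitters' processing notes without a role. The counting program, the gene annotation and the use of strand are not given in the sources used here. Reads of a gene and an overlapping or antisense gene may therefore be counted together: of the 191 named genes with a position, 120 overlap another gene of the RefSeq table. Copies of the ribosomal RNA genes each carry large counts of their own, so reads of identical copies appear to be listed once per copy. Of the rows, 7790 were at 0 in all 6 libraries. These include genes that most human cells use, such as FBL, RPL7A, CANX and TJP1, so a gene at 0 is described here only as listed at 0. No mitochondrially encoded gene is among the rows used here.

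Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 15131 genes, and libraries were scaled with TMM factors. Groups were compared with edgeR's quasi-likelihood F test on all 6 libraries with no other term, and p-values were adjusted by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM values use the TMM-scaled library sizes, and errors beside CPM are SDs over 3 libraries. Total counts ranged from 33499827 to 44466137 per library, and from 27808151 to 29100459 without ribosomal RNA rows.

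Before the data were examined, 47 gene lists were written down, covering innate immunity, stress responses, metabolism, growth signalling, adhesion, the cell cycle, the TRIM21 protein's known partners and markers of other cell types. The 42 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry served as alternatives. The median, mean and test disagreed in sign for 9 lists, none of them called: MHC class I antigen presentation, nucleic acid sensing, NRF2 targets, glycolysis, DNA repair, heat shock response, immediate-early genes, RING-SPRY TRIM paralogs and intestinal differentiation markers.

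The rule for naming genes was also fixed beforehand. It took TRIM21, and per direction the 10 largest changes among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups. It added per direction the 5 smallest p-values, 2 non-coding or unnamed genes, and up to 4 members per list with the smallest p-values. Non-coding or unnamed genes, told by their symbols, were left out of the 10 largest changes and the 5 smallest p-values. They made up 44 of the higher and 60 of the lower genes that met the level and overlap criteria. Of the genes this rule took, 4 are not reported here, and the counts of gene values over the alternatives leave them out. Gene positions are from the RefSeq table of GRCh38.p14. Of the symbols, 26998 (95.5%) matched that table. Transcript length, GC content, coding sequences and 3' UTRs came from GENCODE release 29, which may differ from the annotation the authors used.

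The test was checked on simulated data: in each of 10 simulations, 200 of about as many genes as were tested in the comparison of shTRIM21 with shControl (between 15088 and 15108 after filtering) were changed by known folds. Of the changed genes, 55.6% were recovered at 1.3-fold, 67.0% at 1.5-fold, 87.2% at 2-fold and 98.2% at 4-fold. Unchanged genes made up 8.55% of the calls in these simulations, above the nominal 5%. The data called 3146 genes, far more than the 200 changed here, so these shares need not carry over to the data. Camera recovered a list of 25 genes lowered 1.3-fold in 10 of 10 simulations and called 1 of 420 unchanged lists, in data simulated without correlation between genes.

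Alternatives fixed beforehand were RLE, upper-quartile and unscaled library sizes, no filter on low counts, a filter of at least 50 reads in at least 3 libraries, the replicate number as a block, and leaving out each library. Others were leaving out short structured and histone RNAs, DESeq2 1.42.0, limma-voom, robust empirical Bayes, an adjusted p under 0.01 and glmTreat against a 1.5-fold change. Added after seeing the data were leaving out ribosomal RNA rows, leaving out shControl replicates 1 and 3, and a correction for GC content and transcript length. That correction subtracted a natural spline trend with 4 degrees of freedom per property from each library. A scan of 3' UTRs for 7-base words, symbol families and the tests of technical explanations were run with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, or in R. No 2 libraries were alike within sampling noise: chi-square per degree of freedom over genes was 4.86 to 11.4 within groups and 23.5 to 32.5 between groups.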

Results

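The effect of lowering TRIM21 on the transcriptome was examined in RKO cells, comparing 3 libraries with a hairpin against TRIM21 and 3 with a scrambled hairpin. TRIM21, also called Ro52, is an E3 ubiquitin ligase that also binds antibodies in the cytosol. The shTRIM21 libraries held 34746612, 38051662 and 33499827 counts and the shControl libraries 42055812, 33829727 and 44466137. Ribosomal RNA rows took 19.3%, 23.5% and 16.99% of the counts in shTRIM21 and 31.0%, 14.7% and 36.9% in shControl. The group means of this share, 19.9% ± 3.32 and 27.5% ± 11.5 (SD, n = 3 each), gave p = 0.4 in a two-sided exact permutation test, which with 3 against 3 cannot go below 0.1 and so leaves open whether the share differs. Without these rows the libraries were of nearly equal depth, 27808151 to 29100459 counts.

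TRIM21 itself fell by 31.3% at the transcript level. Its counts were 299, 271 and 297 in the shTRIM21 libraries and 459, 421 and 343 in the shControl libraries. Scaled levels were 7.58 ± 0.574 CPM against 11.03 ± 1.40 CPM (SD, n = 3 each), with the groups not overlapping. The TRIM21 log2 fold change was -0.54 (SE 0.12, 95% interval -0.79 to -0.29; edgeR adjusted p = 0.00424). With library sizes alone in place of TMM factors the change was -0.34 and no longer called (edgeR adjusted p = 0.197, the highest over the alternatives, where the lowest was 0.000399 with no filter on low counts). TRIM21 lies on chromosome 11 at 4384897 to 4393702 (GRCh38.p14), and 0 other annotated genes overlap it. At the level of single genes, 1128 others had a smaller p-value than TRIM21.

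**Figure D1:**
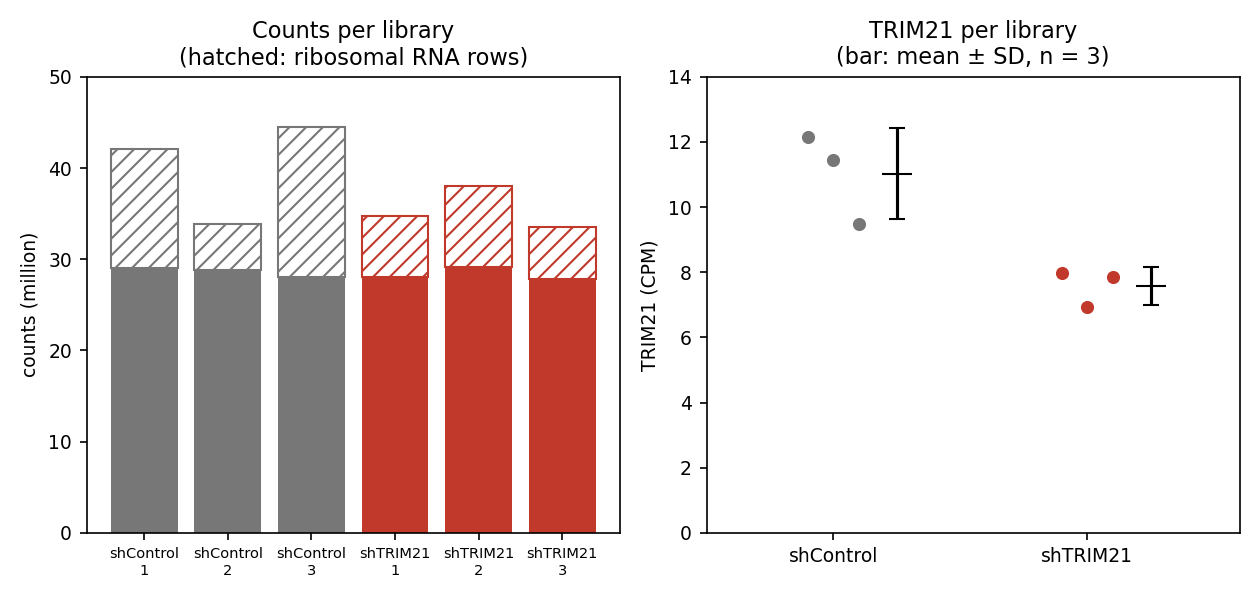
Left, counts per library (y axis, in units of 1e+06 counts), with ribosomal RNA rows hatched, for 3 shControl and 3 shTRIM21 libraries. Right, TRIM21 level per library in CPM, each point 1 library, with the mean and SD beside it (n = 3); the highest shTRIM21 library, at 7.97 CPM, lies below the lowest shControl library, at 9.47 CPM.

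Between the groups, 3146 of 15131 tested genes changed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1479 of them higher and 1667 lower in shTRIM21. Most changes were small. The median size among called genes was 1.28-fold, and 250 genes changed at least 2-fold, 161 higher and 89 lower. The groups did not overlap for 5701 tested genes, 37.7% where chance gives 10%. The first principal component held 45.03% of the variance and separated the groups. Upper-quartile scaling made 62.1% of the calls higher and library sizes alone 93.0%, against 47.0% with TMM; library sizes alone shifted the median of all tested genes to 0.22 on the log2 scale. Leaving out shTRIM21 replicate 2 left 1844 called genes, and leaving out shControl replicates 1 and 3, an alternative added after seeing the data, left 1958.

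**Figure D2:**
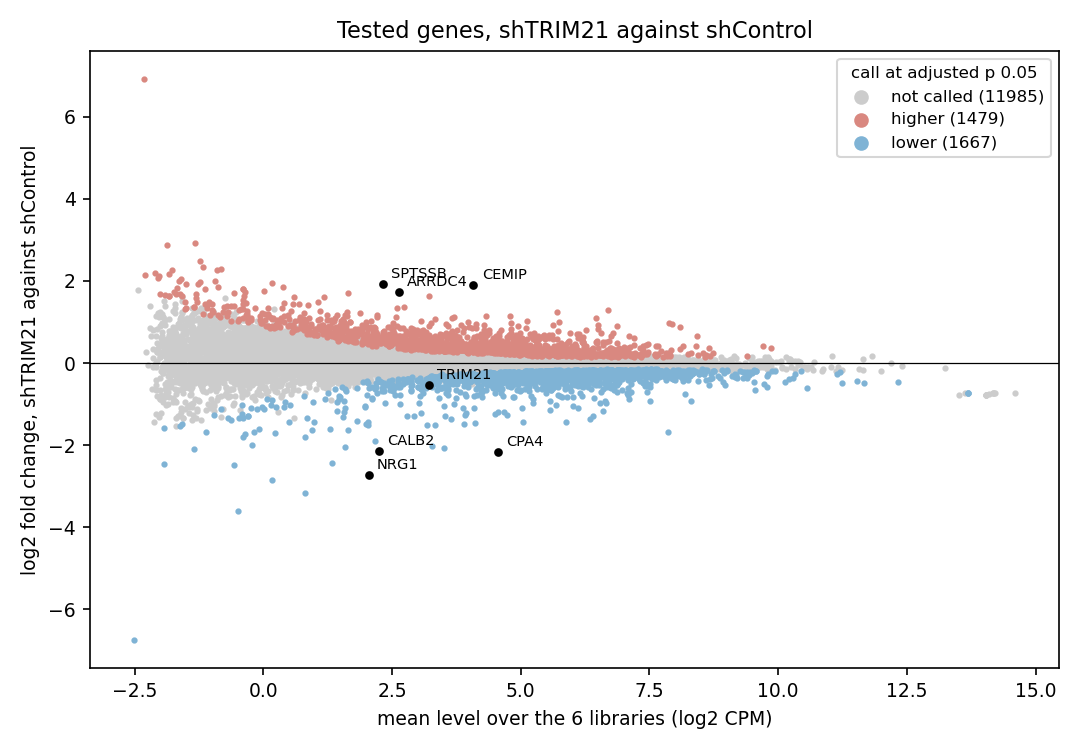
Log2 fold change of shTRIM21 against shControl (y axis) by mean level over the 6 libraries in log2 CPM (x axis) for each of the 15131 tested genes, coloured by call. TRIM21 and the 3 genes with the largest named changes per direction are marked in black; called genes spread on both sides of 0, with 1479 higher and 1667 lower.

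Among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, NRG1 fell most in shTRIM21. NRG1, which encodes an EGF-family ligand of the ERBB receptors, went from 7.17 ± 0.578 to 1.08 ± 0.303 CPM (SD, n = 3), 6.60-fold lower (log2 fold change -2.72, SE 0.19, edgeR adjusted p = 1.78e-07). The carboxypeptidase gene CPA4 was 4.49-fold lower, the calretinin gene CALB2 4.42-fold, the keratin gene KRT7 4.16-fold and the transmembrane collagen gene COL13A1 4.07-fold. CCN2, a matricellular growth factor gene, was 3.72-fold lower. The proteoglycan gene VCAN, the most abundant of these, went from 356 ± 15.9 to 111 ± 12.8 CPM (SD, n = 3). PRICKLE1, of planar cell polarity, KRT80 and the glucose transporter gene SLC2A3 were 2.87-fold, 2.84-fold and 2.84-fold lower. The smallest p-values among the lower genes named were those of CPA4 and VCAN (edgeR adjusted p = 2.78e-09 for both), NT5E, BCAR3 and TNFRSF6B. NT5E, encoding the ecto-nucleotidase CD73, was 2.71-fold lower, BCAR3 2.70-fold and the decoy receptor gene TNFRSF6B 2.58-fold. KRT7 overlaps KRT7-AS, CCN2 overlaps CCN2-AS1, VCAN overlaps VCAN-AS1, BCAR3 overlaps BCAR3-AS1 and TNFRSF6B overlaps the readthrough RTEL1-TNFRSF6B, so their reads may be shared.

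Among the genes that rose, SPTSSB, a small subunit of serine palmitoyltransferase, went from 2.08 ± 0.315 to 7.93 ± 0.462 CPM (SD, n = 3), 3.80-fold higher (log2 fold change 1.93, SE 0.15, edgeR adjusted p = 5.31e-07). CEMIP, whose product acts in hyaluronan breakdown, was 3.73-fold higher, the arrestin-domain gene ARRDC4 3.33-fold and the immunoglobulin-superfamily gene IGSF9 3.11-fold. GFY and the sestrin gene SESN3 were 2.59-fold and 2.52-fold higher. MAN1A1, a Golgi mannosidase gene, went from 59.8 ± 6.10 to 146 ± 3.97 CPM (SD, n = 3) and had the smallest p-value of the higher genes named (edgeR adjusted p = 2.04e-08). ABCC2, an export pump of organic anions, the microtubule-associated gene MAP2 and ARL2BP were 2.37-fold, 2.24-fold and 2.22-fold higher. SAT1, which acetylates polyamines, rose 2.14-fold, the fatty acid elongase gene ELOVL6 2.01-fold and SEPTIN2 1.85-fold. CEMIP overlaps MESD and SEPTIN2 overlaps HDLBP on the annotation. The 3' UTRs of SESN3, ARL2BP, SEPTIN2 and ELOVL6, and of the lower gene CPA4, hold the 7-base word GTGTCAC. Among genes without a protein name, LINC02458 and C14orf132 were 2.34-fold and 1.99-fold higher, and C1orf116 and RN7SL2 were 2.34-fold and 2.39-fold lower. RN7SL2 lost its call with robust empirical Bayes.

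**Figure D3:**
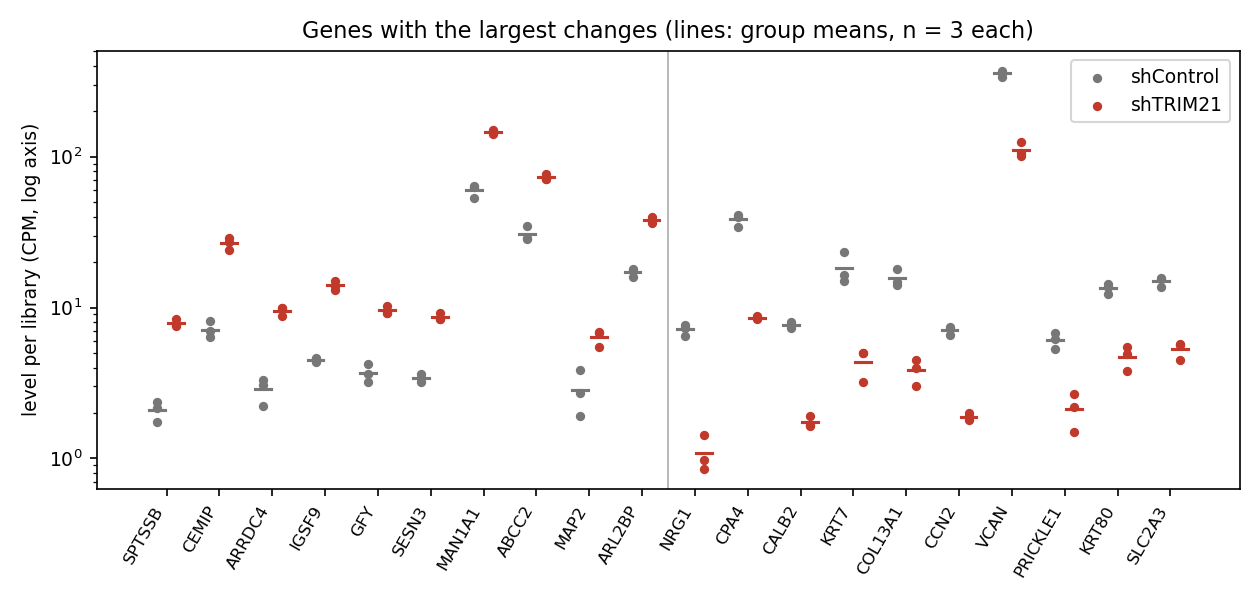
Level per library in CPM on a log axis (y axis) for the 10 genes with the largest rise (left of the line) and the 10 with the largest fall (right) in shTRIM21 among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, with non-coding or unnamed genes left out; points are libraries and horizontal lines group means (n = 3 each). NRG1 fell from 7.17 to 1.08 CPM and SPTSSB rose from 2.08 to 7.93 CPM, and the 3 libraries of a group do not overlap those of the other for any gene shown.

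Of the 42 gene lists tested, camera with a preset correlation called 13, 11 lower and 2 higher in shTRIM21. With an estimated correlation camera called 0, and 5 lists had an unadjusted p under 0.05. Fry called 20. Over the 13 lists the estimated correlation ran from -0.0079 (p53 targets) to 0.57 (ribosome biogenesis), against the preset 0.01. The camera p-values at the preset correlation take members as nearly uncorrelated and measure the spread over genes. The lists share some members, such as AXL, SLC7A11 and LIF. Under library sizes alone the medians of 7 of the 13 lists changed sign, each named below with its value, while the median of all tested genes was 0.22 there. Of the 161 called genes named by rule, 74 were not called under library sizes alone, among them ATF4, ASNS, PHGDH, CCND1, CDKN1A, PLK1 and BOP1. Over all 3146 called genes, 46.9% kept their call under library sizes alone and 83.9% with upper-quartile factors. RLE kept 99.2%, and leaving out ribosomal RNA rows kept 98.5%.

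Target genes of the transcription co-activators YAP and TAZ fell together. Of 22 tested members, 14 fell and 0 rose (16 and 1 adjusted over the list alone), with a median log2 fold change of -0.53 (camera adjusted p = 6.83e-27; adjusted p = 0.0718 with an estimated correlation). NT5E changed by -1.44 (SE 0.066), the angiomotin-like gene AMOTL2 by -1.05 (SE 0.065), the receptor tyrosine kinase gene AXL by -0.92 (SE 0.072) and CRIM1 by -0.87 (SE 0.063), with edgeR adjusted p-values of 4.78e-09, 6.50e-08, 4.84e-07 and 2.04e-07. The 3' UTR of AXL holds GTGTCAC. The fall was also called with every scaling tried, the smallest median being -0.31 with library sizes alone.

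Genes of the ATF4 branch of the integrated stress response, which cells induce when amino acids are short, also fell: 19 of 24 were lower and 0 higher (19 and 0 adjusted over the list alone). Their median log2 fold change was -0.42 (camera adjusted p = 2.54e-19; adjusted p = 0.147 with an estimated correlation), and -0.21 with library sizes alone. The cystine transporter gene SLC7A11 changed by -1.14 (SE 0.080), the glutathione-degrading enzyme gene CHAC1 by -1.48 (SE 0.12), ATF4 itself by -0.53 (SE 0.053) and the asparagine synthetase gene ASNS by -0.54 (SE 0.063). SLC7A11 overlaps SLC7A11-AS1. In the serine, one-carbon and nucleotide list 12 of 23 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.17 and 0.033 with library sizes alone (camera adjusted p = 3.13e-05; adjusted p = 0.455 with an estimated correlation). PSAT1 and PHGDH, of serine synthesis, changed by -0.71 (SE 0.062) and -0.45 (SE 0.054), the purine synthesis gene PFAS by -0.61 (SE 0.068) and the mitochondrial folate enzyme gene MTHFD1L by -0.37 (SE 0.058).

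Genes transcribed downstream of MAPK signalling were lower for 12 and higher for 3 of 24 members (14 and 4 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 8.65e-09; adjusted p = 0.0718 with an estimated correlation). Under library sizes alone this median was -0.010. EPHA2, MYEOV, LIF and CCND1 changed by -0.92 (SE 0.059), -0.84 (SE 0.057), -0.71 (SE 0.053) and -0.65 (SE 0.060). Of 29 genes in the list of integrins, laminins and collagens, which also holds other matrix genes, 12 fell and 2 rose (12 and 3 adjusted over the list alone), with a median of -0.12, which was -0.076 without shTRIM21 replicate 1, -0.080 with upper-quartile factors, -0.20 with no filter on low counts and 0.098 with library sizes alone (camera adjusted p = 6.72e-06; adjusted p = 0.455 with an estimated correlation). COL12A1, the thrombospondin gene THBS1 and the integrin gene ITGA6 changed by -0.96 (SE 0.067), -1.26 (SE 0.092) and -0.66 (SE 0.063). Among 15 mesenchymal genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.23 and -0.014 with library sizes alone (camera adjusted p = 0.00411; adjusted p = 0.455 with an estimated correlation). Vimentin, VIM, which overlaps VIM-AS1, changed by -1.07 (SE 0.18) and ITGA5 by -0.32 (SE 0.062), the latter not called with library sizes alone. The fibronectin gene FN1 rose by 0.45 (SE 0.12), a call lost without shTRIM21 replicate 2 or without shControl replicate 3. Without shControl replicates 1 and 3 the mesenchymal list was not called (camera adjusted p = 0.0517, from a range of 0.000215 to 0.455 over its alternatives).

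The cell cycle and ribosome biogenesis lists were called lower by camera with small medians and most of their members uncalled; none of these 3 lists was called with library sizes alone, where the medians were positive. Of 40 G2/M and mitosis genes 15 fell and 1 rose (17 and 3 adjusted over the list alone), with a median of -0.15 and 0.061 with library sizes alone (camera adjusted p = 0.00242; adjusted p = 0.147 with an estimated correlation). HMMR, KIF2C and the mitotic kinase gene PLK1 changed by -0.52 (SE 0.060), -0.35 (SE 0.054) and -0.26 (SE 0.050). Of 40 DNA replication and G1/S genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.13 and 0.083 with library sizes alone (camera adjusted p = 0.018; adjusted p = 0.54 with an estimated correlation). E2F8 and UHRF1 changed by -0.50 (SE 0.076) and -0.33 (SE 0.054). The replicative helicase gene MCM6, whose 3' UTR holds GTGTCAC, was the exception at 0.93 (SE 0.062). This list was also not called without shTRIM21 replicate 3 or without shControl replicate 2. Of 35 ribosome biogenesis genes 12 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.13 and 0.074 with library sizes alone (camera adjusted p = 0.00501; adjusted p = 0.759 with an estimated correlation). RRP12, BOP1 and UTP20 changed by -0.37 (SE 0.060), -0.29 (SE 0.057) and -0.37 (SE 0.075). The median was -0.20 without shControl replicate 1 and -0.23 without shControl replicates 1 and 3. The list was also not called without shControl replicate 2 (median -0.075) or by fry.

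Of 32 p53 target genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.097, which was -0.055 with upper-quartile factors and 0.12, not called, with library sizes alone (camera adjusted p = 0.0109; adjusted p = 0.226 with an estimated correlation). The cyclin-dependent kinase inhibitor gene CDKN1A, PLK3 and GDF15 changed by -0.39 (SE 0.055), -0.52 (SE 0.081) and -0.39 (SE 0.067). Of 24 cholesterol synthesis genes and SREBP2 targets 11 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.18 and 0.042, not called, with library sizes alone (camera adjusted p = 0.00501; adjusted p = 0.54 with an estimated correlation). The enzyme genes MVK and IDI1 changed by -0.44 (SE 0.076) and -0.41 (SE 0.072), and TM7SF2 rose by 0.44 (SE 0.081). This list was not called without shControl replicates 1 and 3.

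The lists called higher were the hypoxia response and the neuroendocrine and neuronal genes. Of 25 hypoxia-response genes 9 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.22 and 0.42 with library sizes alone (camera adjusted p = 0.00106; adjusted p = 0.455 with an estimated correlation). The oxidoreductase gene ERO1A, whose 3' UTR holds GTGTCAC, changed by 0.63 (SE 0.062), ANGPTL4 by 0.98 (SE 0.13), MXI1 by 0.44 (SE 0.061) and the collagen lysyl hydroxylase gene PLOD2 by 0.50 (SE 0.084). Of 8 neuroendocrine and neuronal genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.12, which was 0.34 with library sizes alone and 0.27 without shControl replicates 1 and 3 (camera adjusted p = 0.047; adjusted p = 0.54 with an estimated correlation). The enolase gene ENO2, whose 3' UTR holds GTGTCAC, MAP2 and the tubulin gene TUBB3 changed by 1.02 (SE 0.065), 1.17 (SE 0.21) and 0.21 (SE 0.056), and STMN3 by -0.33 (SE 0.052). TUBB3 was not called without shTRIM21 replicate 2 or without shControl replicate 2. The call of the list was lost without shTRIM21 replicate 1 (median 0.10), shTRIM21 replicate 3 (0.092) or shControl replicate 2 (0.065), by fry and after the GC and length correction. With no filter on low counts it was also lost and the median turned to -0.16.

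**Figure D4:**
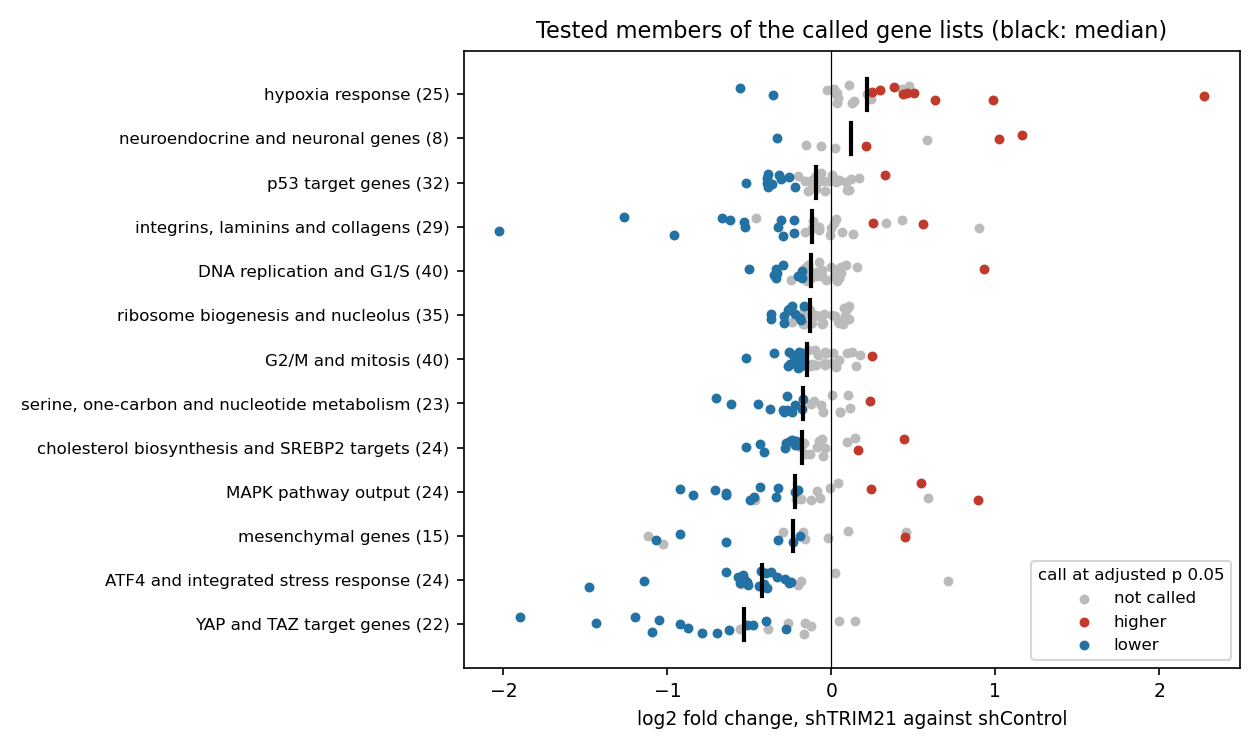
Log2 fold change of shTRIM21 against shControl (x axis) for tested members of the 13 called gene lists (rows, with the number tested), coloured by call; black lines are medians. The medians run from -0.53 for YAP and TAZ targets to 0.22 for the hypoxia response, and members of most lists lie on both sides of 0.

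The other 29 lists were not called by camera with a preset correlation. Among them fry called the interferon-stimulated, NF-kB, TGF-beta and BMP, epithelial, matrix protease, apoptosis, inflammasome and necroptosis, TRIM21 partner and nuclear long non-coding RNA lists, with fry adjusted p-values from 0.00479 to 0.0497; fry does not compare a list with other genes. Of 41 interferon-stimulated genes 10 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.0919), IFIT1 by 0.84 (SE 0.16) and SP110 by 0.76 (SE 0.16), while DTX3L changed by -0.53 (SE 0.096). MHC class I antigen presentation had 3 higher and 3 lower of 18 (4 and 3 adjusted over the list alone), with TAPBP at -0.38 (SE 0.067). Nucleic acid sensing had 4 higher and 1 lower of 19 (4 and 3 adjusted over the list alone), with STING1 at 0.54 (SE 0.093). Of 23 NF-kB targets 2 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.0659), NFKBIA by -0.63 (SE 0.088). Among 29 partners and substrates of the TRIM21 protein 1 rose and 7 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.103, fry adjusted p = 0.00479), the Ro60 gene RO60 by -0.41 (SE 0.088). Among 21 TRIM paralogs 2 rose and 2 fell (2 and 2 adjusted over the list alone), with TRIM27 at -0.52 (SE 0.056). TRIM34, which overlaps TRIM5 and the readthrough TRIM6-TRIM34, was at 1.18 (SE 0.31). Its call was lost without shTRIM21 replicate 2 or without shControl replicate 2.

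Epithelial genes moved both ways: 13 of 31 rose and 6 fell (15 and 6 adjusted over the list alone; camera adjusted p = 0.198). The E-cadherin gene CDH1 was at 0.57 (SE 0.068) and KRT23 at 1.14 (SE 0.091), against KRT80 at -1.51 (SE 0.13). Wnt targets had 5 higher and 4 lower of 19 (5 and 4 adjusted over the list alone), with SOX4 at 0.89 (SE 0.060), AXIN2 at 0.49 (SE 0.082), CCND1 at -0.65 (SE 0.060) and DKK1 at -0.55 (SE 0.060). TGF-beta and BMP targets had 6 higher and 2 lower of 16 (6 and 2 adjusted over the list alone). Matrix proteases and inhibitors had 3 higher and 6 lower of 19 (4 and 6 adjusted over the list alone), with the urokinase gene PLAU at -0.64 (SE 0.064). Among 6 intestinal differentiation markers 0 rose and 1 fell (0 and 1 adjusted over the list alone), the carbonic anhydrase gene CA2, at -0.61 (SE 0.075).

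In metabolism, NRF2 targets had 5 higher and 6 lower of 25 (6 and 6 adjusted over the list alone), led by ABCC2 at 1.25 (SE 0.077) and SLC7A11 at -1.14 (SE 0.080). Glycolysis had 4 higher and 3 lower of 22 (4 and 4 adjusted over the list alone). Fatty acid synthesis had 3 higher and 6 lower of 21 (3 and 7 adjusted over the list alone), with the desaturase gene SCD at -0.36 (SE 0.067). Ferroptosis and iron handling had 3 higher and 5 lower of 22 (5 and 5 adjusted over the list alone), with the transferrin receptor gene TFRC, whose 3' UTR holds GTGTCAC, at 0.95 (SE 0.071). Oxidative phosphorylation had 0 higher and 9 lower of 70 (0 and 4 adjusted over the list alone). Autophagy had 2 higher and 4 lower of 29 (2 and 4 adjusted over the list alone), with ATG12 at -0.91 (SE 0.059). Lysosome genes had 2 higher and 6 lower of 34 (2 and 8 adjusted over the list alone).

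For stress and cell death, apoptosis regulators had 1 higher and 5 lower of 33 (1 and 4 adjusted over the list alone), with BCL2L1 at -0.76 (SE 0.049) and PMAIP1 at -0.83 (SE 0.076). Inflammasome and necroptosis genes had 2 higher and 2 lower of 13 (3 and 2 adjusted over the list alone), with the gasdermin gene GSDME at 0.71 (SE 0.12). Endoplasmic reticulum chaperones had 2 higher and 1 lower of 20 (2 and 1 adjusted over the list alone) and heat shock genes 1 higher and 2 lower of 19 (1 and 2 adjusted over the list alone). Immediate-early genes had 1 higher and 3 lower of 21 (2 and 3 adjusted over the list alone), with EGR1 at 0.58 (SE 0.070) and ATF3, whose 3' UTR holds GTGTCAC, at -0.65 (SE 0.085). DNA repair had 2 higher and 0 lower of 30 (2 and 0 adjusted over the list alone), with ATM at 0.34 (SE 0.083).

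Cytosolic ribosomal protein genes had 0 higher and 5 lower of 77 (0 and 0 adjusted over the list alone). Of 14 histone genes and 7 cancer-testis antigen genes 0 were called by edgeR, adjusted over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Short structured RNAs had 0 higher and 3 lower of 14 (0 and 3 adjusted over the list alone), with RN7SL1 at -1.10 (SE 0.19) and RNA28SN5 at -0.72 (SE 0.25), in libraries whose ribosomal RNA share ranged from 14.7% to 36.9%. Without shControl replicates 1 and 3, the libraries with the highest share, RNA28SN5 turned to 0.23 and was not called, and RN7SL1 lost its call. RNA28SN5 was called in 3 of 16 alternatives, and RN7SL1 also lost its call with robust empirical Bayes. With library sizes alone the ribosomal protein gene RPL35 turned from -0.19 to 0.014 and TRIM65 from -0.21 to 0.0034, neither of them called there. Nuclear-retained long non-coding RNAs had 5 higher and 1 lower of 22 (5 and 1 adjusted over the list alone), with NEAT1 at 0.66 (SE 0.088) and TUG1 at 0.39 (SE 0.066).

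Few markers of other cell types passed the filter on low counts. Of the fibroblast markers 4 were tested and 1 rose (2 adjusted over the list alone), the smooth muscle gene TAGLN, at 0.45 (SE 0.085). Among the 3 endothelial, 2 leukocyte and 2 erythroid markers tested, 0 were called by edgeR over all genes, and 1 leukocyte marker, CD68, had an unadjusted p under 0.05 and was lower adjusted over the list alone. None of these lists reached the 5 tested members needed for camera, nor did the mitochondrially encoded genes, with 0 tested.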

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

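Leaving out ribosomal RNA rows, leaving out shControl replicates 1 and 3, and the GC and length correction were chosen after seeing the data; in the second of these the lone control is assumed to vary like the shTRIM21 libraries. Over all alternatives and named genes, 3281 values kept their direction and side of the threshold, 183 lost the call, 32 gained one, 3 called values changed sign and 29 changed sign without a call either way. Over gene lists, with the direction that of the test, 649 values kept theirs, 30 lost the call, 29 gained one and 44 changed sign without a call either way.

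Leaving out 1 library, which leaves fewer samples, gave 1844 to 2592 genes called, 841 to 1211 genes called higher and 1003 to 1398 genes called lower; the lowest values came without shTRIM21 replicate 2. Without shControl replicates 1 and 3 there were 1958, with 854 higher and 1104 lower, and RNA28SN5 was at 0.23. With library sizes alone there were 1969 genes called, 138 of them lower, and 424 genes called with at least a 2-fold change; TRIM21 was at -0.34, and RPL35 and TRIM65 turned from lower to 0.014 and 0.0034, neither of them called. The median of all genes was 0.22 there. Those library sizes include ribosomal RNA rows, on average 27.5% of counts in shControl and 19.9% in shTRIM21. The share was lowest in shControl replicate 2, at 14.7%. Depth without these rows was nearly equal, 27808151 to 29100459 counts. Dividing by total counts therefore raised other genes in shTRIM21 on average. Unscaled library sizes without these rows were not tried, so how much of the 0.22 this explains was not tested. The filter of 50 reads, which tests fewer genes, left 126 genes changed at least 2-fold. An adjusted p under 0.01 left 1582 genes, 703 higher and 879 lower, and glmTreat 103, 39 higher and 64 lower, as stricter criteria do. Camera with an estimated correlation called 0 lists and fry 20; for RNA28SN5 and these list counts the cause was not tested. With the replicate number as a block 2905 genes were called, and 2813 of these were called without it. Libraries with the same number did not deviate together (correlations -0.081 to -0.027 over 3 pairs), and 0 of the 6 libraries correlated best with their own number. TRIM21, at 271 to 459 counts per library, limits how precisely its fall is known.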

Other observations

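Symbol families were grouped and tested after the data were seen: 273 families with at least 8 tested members, of which camera with a preset correlation called 10 and with an estimated correlation 0 (4 with an unadjusted p under 0.05). Among 17 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 11 fell and 1 rose, with a median of -0.24, or -0.025 with library sizes alone (camera adjusted p = 3.17e-06; adjusted p = 0.998 with an estimated correlation). MARS1 and CARS1 were at -0.51 (SE 0.049) and -0.57 (SE 0.063), and RARS1, the exception, at 0.20 (SE 0.058). AARS1, GARS1, WARS1 and SARS1 are also in the ATF4 list. Among 11 HOXB genes and antisense transcripts, neighbours in 1 cluster on chromosome 17, 7 fell and 0 rose, with a median of -0.37, or -0.17 with library sizes alone (camera adjusted p = 0.000142; adjusted p = 0.952 with an estimated correlation). HOXB4 was at -0.79 (SE 0.079) and HOXB8 at -0.63 (SE 0.061).

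Among 15 keratin rows, 1 of them the antisense KRT7-AS, 8 fell and 1 rose, with a median of -0.44, or -0.23 with library sizes alone (camera adjusted p = 0.00011; adjusted p = 0.998 with an estimated correlation). KRT18, KRT8 and KRT19, keratins of simple epithelia, were at -0.46 (SE 0.065), -0.44 (SE 0.080) and -0.38 (SE 0.059), and KRT81, which was below 5 CPM in both groups, at -3.61 (SE 0.42), while KRT23 rose by 1.14 (SE 0.091). Of 416 zinc finger genes with ZNF symbols 48 rose and 12 fell, with a median of 0.12, or 0.33 with library sizes alone (camera adjusted p = 0.0295; adjusted p = 0.998 with an estimated correlation). All 13 protocadherin alpha genes tested rose by similar amounts, with a median of 0.53; they share exons, so these are not separate measurements.

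For the 3 patterns weighed next, the tests by splits for genes, by a scrambled sequence in wide use, by a following A and by the GC and length correction were chosen after the result was seen, and the word GTGTCAC was itself picked from the data.

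The 3146 called genes were weighed first. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: the real split called 3146 genes, 1 of 10 to reach that number, and the highest other split called 0 with edgeR (175 to 446 at an unadjusted p under 0.05). Each other split puts libraries of both arms on each side, so it holds part of the group difference and adds the rest to the spread. Against residual ribosomal RNA as the whole cause, shControl replicate 2, the library with the least of it, lay on the shControl side for 87.0% of the genes called without it. Against GC content and transcript length, the correction was compared with an uncorrected fit to the same 14567 genes with GC and length values. Of 3230 calls in that fit, 97.9% stayed called in the same direction. Of the 3146 called genes, 96.3% kept their call and direction. Against chromosome-scale copy number differences, 0.26% of called genes lay in the 2 windows of 10 Mb with a median change beyond 0.3. Effects of lower TRIM21, of either hairpin and of selecting separate cell pools stay open, as each arm holds 1 hairpin as far as the labels say.

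The second pattern is the fall of YAP and TAZ targets. For gene lists the real split called 13, 1 of 10 splits to do so, and the highest other split called 9, too few splits for a share under 0.05. Fry called 20 lists in the real split and 0 in the others. These counts are over all lists. Those of camera do not show whether the YAP and TAZ list was called in the other splits. The other splits call 0 genes by edgeR but still hold part of the group difference. Whether their preset-correlation camera calls would arise without such a difference therefore cannot be told. The list kept 103% of its median after the GC and length correction, and no 7-base word of the TRIM21 transcript, where the hairpin's seed match would lie, passed a Bonferroni threshold for lower values, so 0% of the list's 21 members with a 3' UTR held one. That 0% follows once no word passes, and the scan sees only a word of TRIM21 that acts in many 3' UTRs. The word TATTTAT, not in TRIM21, went with lower values by -0.050 (held by 3981 of 12738 genes) and is held by 15 of the 21, against the list's median of -0.53; what AU-rich words add to the fall was not tested. Other effects of either hairpin, a response to lower TRIM21 and a difference between the cell pools, such as in density or attachment, remain open and were not tested.

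The third pattern came from a scan of 15729 words in the 3' UTRs of 12738 genes, with length and GC content as terms. GTGTCAC went with higher values in shTRIM21, by 0.097 (SE 0.012, n = 1091 genes with the word; Bonferroni p = 1.3e-12, where 2 of 20 permutations of the genes gave a word past the threshold, the smallest p being 0.00506), in 9 of 9 pairs of libraries between groups, which are not independent; 18.3% of the higher genes held it, against 5.92% of the lower and 7.66% of the uncalled. This SE and p measure the spread over genes, not over libraries. Splitting the libraries by arm gave an effect of 0.095, and the largest size in the other splits was 0.051. The word was picked on this same comparison, which favours the split by arm and the 9 of 9 pairs. Each other split also holds only part of the group difference, so these values are no separate support. Against GC content and transcript length, the difference between genes with and without the word kept 101% of its size after the correction. That difference was taken with no length or GC terms. Against zinc finger paralogs, 101% of the effect was kept without genes whose symbols start with ZNF. Zinc finger genes under other symbols stayed in. A candidate explanation is a seed of the scrambled hairpin that lowers these genes in shControl. In coding sequences alone the word had an effect of 0.026 (SE 0.012), 27.1% of that in 3' UTRs. A following A went with a further 0.056 (SE 0.023). The word was picked for its 3' UTR effect, so a smaller coding effect was likely beforehand. Any element that acts through 3' UTRs could give it, so it does not single out a hairpin seed. A scrambled target in wide use, TTCTCCGAACGTGTCACGT, was picked because it holds the word, 1 of its 11 tested words to pass, so this decides nothing. Its word TGTCACG, opposite guide positions 2 to 8 if the guide spans the whole target, had an effect of 0.00038 and did not pass. GTGTCAC lies 1 base from TGTCACG in that target, and where a guide would start is not known here. The value for TGTCACG therefore decides nothing either, and the hairpin used here and any change in a microRNA stay open.

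The fall of TRIM21 reached at most -0.55 over RLE, upper-quartile, unscaled and ribosomal RNA-free scaling, and 0 annotated genes overlap it.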
